A study of Mus musculus with 2 samples.

How the data were processed

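The data were ATAC-seq peak lists from 2 samples of embryonic mouse stomach (strain B6NCrl, 15.5 days), 1 group with 2 biological replicates. Replicate 1 was a pool of 78 embryos and replicate 2 a pool of 62, both of mixed sex, and the labels give both pools 1 donor label. DNA was fragmented by tagmentation and selected at 200 to 750 bp, per the labels. No reads, alignments or signal tracks were used here. The number of reads per sample is not given in the sources used here, so the depth and the precision it sets are unknown. The intervals in the report cover the number of regions alone.

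All lists are in the narrowPeak layout on mm10, and the authors derived them from filtered alignments and, except for the ranked lists, an exclusion list, per the submitters' processing notes. The aligner and the peak caller are not given in the sources used here. Column 7 holds the signal of each peak as deposited. Its scale, and whether it is relative to a background, are not stated in the sources used here. Columns 8 and 9 hold the −log10 p-value and −log10 q-value as deposited. Column 5 holds a score, which in the lists the authors thresholded by IDR (the irreproducible discovery rate) was never below 540. The authors deposited IDR-thresholded, IDR-ranked and pseudoreplicated lists for each replicate; the pseudoreplicated lists held scores down to 20 and so passed no such threshold. For both replicates together they deposited IDR-thresholded, conservative IDR, replicated, pseudoreplicated and ranked lists. In the list ranked between replicates, columns 15 and 19 hold a −log10 p-value for each replicate as deposited, without naming the replicate.

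The IDR-thresholded lists held 23194 peaks for replicate 1 and 40394 for replicate 2, and the pseudoreplicated lists 52411 and 91922. The conservative list held 40454 peaks, which merged to 18411 regions. The ratio of peaks between the replicates was 1.74, and that of the IDR-thresholded list of both replicates over the conservative one 1.16. Overlapping peaks of a list were merged into regions on chromosomes 1 to 19, X and Y. Coordinates were written 1-based. Genes and start sites came from GENCODE M21 and sequence from GRCm38.p6, the build of mm10. No region or start site lay beyond a chromosome end of that sequence.

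Regions of the replicates were matched where at least 0.5 of either was covered, and the shares were set against 100 random placements of a list on the same chromosomes (one-sided permutation test). Rank correlation was computed over the list ranked between replicates, with 100 bootstrap draws of peaks for the interval. A region was a promoter region if it overlapped 1 kb on either side of a start site of any gene, and otherwise took the class of its midpoint. Shares of regions have exact binomial 95% intervals. Distal regions were assigned to the nearest protein-coding start site within 100 kb.

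Before the data were examined, 28 gene lists with 451 entries were fixed. They cover stomach cells (epithelium regulators, mature epithelium, squamous forestomach, mesenchyme, smooth muscle, enteric nervous system, pacemaker cells, mesothelium, endothelium) and blood (red and white). They also cover other organs (intestine, pancreas, liver, lung, heart, skeletal muscle, forebrain, kidney), pathways (hedgehog, Wnt, BMP and TGF-beta, extracellular matrix, cell division), housekeeping genes and 3 Hox groups. Each list's share of genes with a promoter region, or mean number of distal regions, was averaged over the 2 replicates. It was set against 10000 random lists of coding genes of the same size, matched on 10 groups of promoter CpG ratio or of assignable bases (two-sided permutation test, Benjamini-Hochberg over the 28 lists, threshold 0.05). The random lists measure chance over genes, not over embryos. Promoter CpG ratio was the highest over a gene's coding start sites, 500 bp on either side. Hox groups were compared with Fisher's exact test, two-sided.

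One symbol of the intestine list was corrected after the lists had first been run. The older symbol Si, written for sucrase-isomaltase, had been matched to the pigment gene Pmel, and was replaced by Sis. With Pmel, the promoter test had 2 lists above and 10 below chance, and with Sis 3 and 11. The 2 calls absent with Pmel were intestine itself (13.3% against 31.5%, permutation adjusted p = 0.0635) and, through the adjustment over all lists, stomach epithelium (adjusted p = 0.0513). The former is kept as an added alternative.

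For motifs, 35 consensus sequences were searched on both strands within 100 bp of distal summits (2497 in replicate 1, 7156 in replicate 2) and in 2 flanking windows centred 600 bp away. A motif was called where the ratio was over 1.2, or under its inverse, and the counting interval excluded 1 in both replicates after Bonferroni correction. Motifs with a count of 0 in a replicate's summits or flanks got no mean ratio and were not ranked.

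Named genes followed a rule fixed before the data were examined. It takes a fixed set of gut regulators, up to 3 genes of each list that passed a test, the 10 genes with most distal regions, and the 10 strongest regions of the conservative list with their nearest gene. It also takes up to 3 genes without a region from each stomach cell list, the 5 most enriched motifs and the 2 most depleted.

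Alternatives fixed beforehand were other overlap rules, a promoter window of 500 bp or 2 kb, assignment within 25 or 500 kb, no matching, pseudoreplicated or conservative lists, and a −log10 q of at least 10. The others were equal numbers of top peaks, single peaks, coding start sites, a motif window of 50 bp, GC-matched motif background in bins of 2% and each replicate left out. Added after the data were seen were equal numbers of top peaks for the gene lists and Pmel in place of Sis. The strongest regions were searched in the nuclear and mitochondrial genomes with BLAST 2.17.0 (megablast, identity of at least 90%), beside 100 random regions of the conservative list.

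The steps were tested on simulated data. With a match planted in 60.0% of 11633 regions, the overlap step returned 60.1%. Of unchanged random lists, 3% (promoter) and 4% (distal) had a p under 0.05, and of lists with planted changes 72% (promoter) and 94% (distal) did, over 21829 genes. The motif step returned 10.98% of 5000 windows where 10.96% held the motif. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Peaks on other sequences of the assembly were kept in the ranked lists alone. They were dropped from the other lists before counting, so their absence there says nothing.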

Results

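ATAC-seq, which inserts sequencing adapters where chromatin is accessible, was run on stomach tissue from mouse embryos at 15.5 days of development. The series held 1 group with 2 biological replicates. Replicate 1 was a pool of stomachs from 78 embryos and replicate 2 a pool from 62 embryos, each of mixed sex. With no second tissue, age or treatment, the design allowed a comparison of the replicates with each other, and of the open regions with chance placement, matched genes and flanking sequence. After overlapping peaks were merged, the lists that passed the authors' reproducibility threshold (IDR) held 11633 regions in replicate 1, covering 8.71 Mb with a median length of 735 bp. Those of replicate 2 held 20016 regions covering 15.02 Mb, with a median of 728 bp. The lists carry no read counts, so the depth of each sample is unknown, and the intervals below cover the number of regions alone. All positions are in the mouse build mm10.

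The first comparison asked how far the pools gave the same open regions. Around Gata4, the gene of a zinc finger transcription factor of the foregut and heart, both replicates listed a region at a start site inside the gene. On chromosome 14 it ran from 63245174 to 63245705 in replicate 1 and from 63245133 to 63245870 in replicate 2. Both also listed a region upstream of Gata4, from 63325845 to 63326623 in replicate 1 and to 63326607 in replicate 2, in an intron of another annotated gene. Regions in Gata4 introns at 63235482 to 63236185 and at 63264601 to 63265132 were listed in replicate 1 and not in replicate 2, although the conservative list of both replicates held an overlapping region at each place.

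Across the genome, 10911 of the 11633 regions of replicate 1 (93.8%, exact binomial 95% interval 93.3 to 94.2) had a match in replicate 2. In the other direction, 10826 of the 20016 regions of replicate 2 (54.1%, 53.4 to 54.8) had a match in replicate 1. Random placement on the same chromosomes gave 0.767% and 0.443% (one-sided permutation test, p = 0.0099 in each direction, the smallest that 100 placements can give). The regions shared 7.93 Mb, a Jaccard index of 50.2%.

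**Figure D1:**
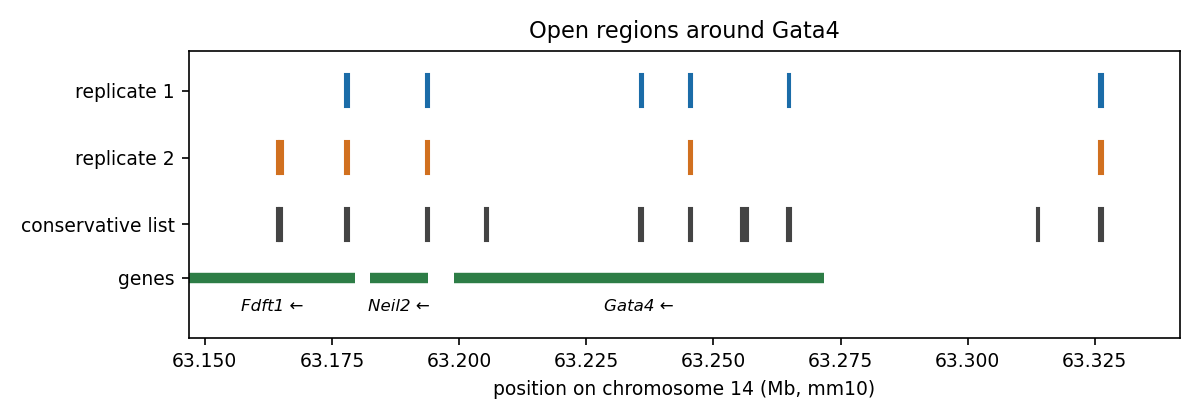
Open regions around Gata4 on chromosome 14 (position in Mb, mm10), drawn to scale for replicate 1, replicate 2 and the conservative list of both replicates, with coding genes as green bars and arrows for their strand. The region from 63325845 is in both replicates and in the conservative list, and 2 regions in Gata4 introns are in replicate 1 and the conservative list.

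The second comparison asked whether peaks ranked alike in the replicates. Over the 91461 peaks ranked between replicates, Spearman's rho of the replicates' −log10 p values was 0.64 (bootstrap 95% interval 0.635 to 0.645), and Pearson's r of their log10 was 0.74. These are correlations across peaks, which are not independent replicates, and no p value for samples follows from them. Among the 47047 peaks away from promoters rho was 0.498, and among the 40656 peaks past the IDR threshold it was 0.679. The list does not name which value belongs to which replicate.

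The third comparison asked where the open regions lie. Promoters, taken as 1 kb on either side of any annotated start site, held 78.5% of the regions of replicate 1 (exact binomial 95% interval 77.8 to 79.3) and 64.2% of replicate 2 (63.6 to 64.9). The mean was 71.4% ± 10.1 (SD, n = 2), and random placement gave 8.46%, a ratio of 8.44 (one-sided permutation test, p = 0.0099 in each replicate, the smallest possible). Introns held 14.1% ± 5.38 of the regions against 39.1% by chance, and intergenic sequence 12.9% ± 4.26 against 49.3%. In the longer pseudoreplicated lists, which passed no IDR threshold, the promoter share was 41.6%.

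**Figure D2:**
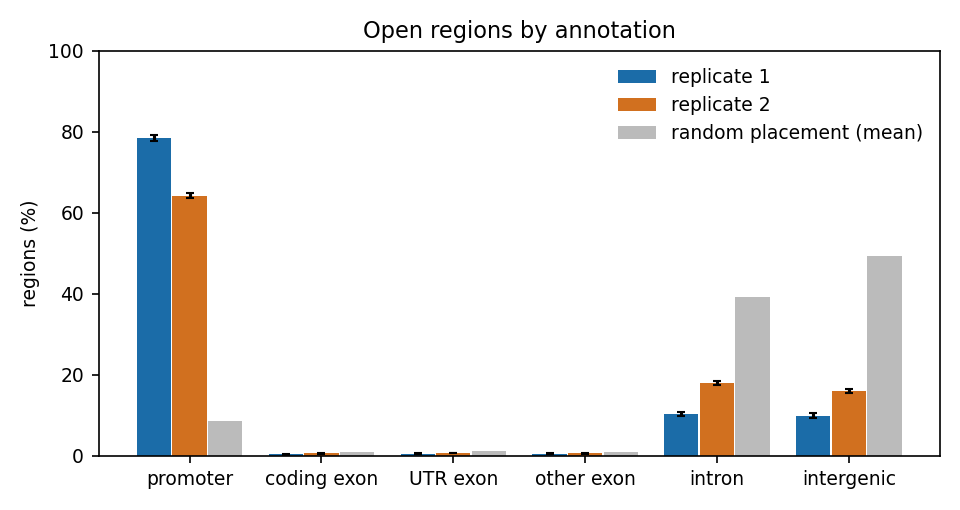
Share of open regions (percent) by annotation class in replicate 1 and replicate 2, with exact binomial 95% intervals, beside the share under random placement. Promoters held 78.5% and 64.2% of regions against 8.46% by chance.

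The regions with the highest values in the authors' signal column of the conservative list were not at the promoters of coding genes. The highest (signal 57.5) lay on chromosome X at 143482936 to 143483180, 35534 bp from the start site of Pak3, the gene of a p21-activated kinase. The next (54.3) lay on chromosome 2 at 69355470 to 69355735, 12986 bp from Abcb11, the gene of the bile salt export pump. The third (46.02) lay on chromosome 10 at 96077546 to 96077951, 58855 bp from Gm5426, and the fourth (43.2) on chromosome 5 at 60042711 to 60043138, 1765892 bp from G6pd2. The other 6 of these 10 lay nearest to Frmd4a (41.5), Tyrp1 (31.1), Myl12b (30.7), Hic2 (30.2), Galc (29.1) and Rtl10 (28.3). The Tyrp1 region, on chromosome 4 at 80002696 to 80003057, was 831247 bp from that gene and at the start site of a gene that is not protein-coding. The nearest of the 10 to its coding start site was 11179 bp away, at Hic2. Of the 10, the regions nearest to Gm5426, G6pd2, Tyrp1 and Galc matched the mitochondrial genome over most of their length, and that nearest to Abcb11 over 48.5%.

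The fourth comparison described the regions with no match in the other replicate. Replicate 1 had 722 of these, of which 26.0% were at promoters (exact binomial 95% interval 22.9 to 29.4), against 82.0% of its matched regions. Replicate 2 had 9190, of which 43.2% were at promoters (42.2 to 44.2), against 82.1% of its matched regions. Unmatched regions were also shorter, with medians of 443.5 bp and 540 bp beside 754 bp and 869 bp for the matched ones. Set against the pseudoreplicated peaks of the other replicate, 65 unmatched regions were left in replicate 1 and 2455 in replicate 2, with promoter shares of 47.7% and 28.4%. With 1 sample on each side, these shares were not tested between replicates.

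The fifth comparison asked which known gene groups had open promoters. Red blood cell genes, whose products make and carry haemoglobin or shape the red cell, had a promoter region in 63.3% ± 23.6 of 15 genes (SD, n = 2), against 13.8% for random genes of matched CpG content. Among them were Gypa, which encodes glycophorin A, Hbb-bt, an adult beta globin, and Epor, the erythropoietin receptor, all open in both replicates. Klf1, the erythroid Krüppel-like factor, was open in both as well, while Gata1 and Alas2 had no promoter region in either. Gata1 had the most distal regions of the list, all of them in replicate 2. With pseudoreplicated peaks 14 of the 15 genes had a promoter region in each replicate. The cell division list had a promoter region in 97.2% ± 3.93 of 18 genes against 77.7%. It includes Ccne1 (cyclin E1), Rrm2 (a subunit of ribonucleotide reductase) and Cdk1 (the mitotic kinase), each open in both replicates.

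Regulators and markers of stomach epithelium had a promoter region in 72.9% ± 8.84 of 24 genes against 54.6%. Of these, 16 were open in both replicates, among them Sox2, a transcription factor of the foregut, Elf3, an epithelial ETS factor, Foxa2, a forkhead factor of endoderm, and Grhl2, a factor of epithelial junctions. Hnf4a, a nuclear receptor of gut epithelium, had a promoter region in replicate 2 alone, and Shh, the hedgehog ligand of gut epithelium, in neither. Both replicates lay above the mean of the matched random lists for these 3 groups. The permutation test over 28 lists gave adjusted p = 0.00112 for red blood cells, 0.0285 for cell division and 0.0476 for stomach epithelium.

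Of the lists, 11 lay below chance in this test. Hox genes of paralogue groups 1 to 5 had a promoter region in 10.0% ± 4.71 of 15 genes against 57.2%, and those of groups 6 to 9 and 10 to 13 in 0% of 12 genes each, against 75.4% and 69.5%. Forebrain genes had one in 13.3% ± 9.43 of 15 against 65.7%, with Lhx2, a LIM homeodomain factor, the only one open in both replicates. These 4 lists had adjusted p = 0.00112 in the permutation test, from an unadjusted p of 0.0002 that is the smallest the 10000 random lists can give, as it was for red blood cells. Hox genes lie side by side in clusters A to D, while the random lists drew genes independently. The p values of the Hox lists therefore treat neighbouring genes as independent.

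Stomach mesenchyme genes had a promoter region in 46% ± 25.5 of 25 against 72.2% (permutation test, adjusted p = 0.004). Meis1, Isl1 and Pbx1, which encode homeodomain factors, were open in both replicates. Barx1, the homeobox gene of stomach mesenchyme, and Foxf1, a forkhead factor of gut mesenchyme, were open in replicate 2 alone, and Foxf2, Nkx2-3 and Nkx2-5 had no region in either. With pseudoreplicated peaks 21 of the 25 mesenchyme genes had a promoter region in replicate 1 and 24 in replicate 2. Wnt pathway genes had a promoter region in 45.5% ± 6.43 of 22 against 73.4% (permutation adjusted p = 0.0049), with Tcf7l2, Ctnnb1, which encodes beta-catenin, and the receptor gene Fzd2 open in both.

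Enteric nervous system genes had one in 18.4% ± 11.2 of 19 against 49.6% (permutation adjusted p = 0.00187). Elavl4, a neuronal RNA-binding protein gene, and Erbb3, a neuregulin receptor gene, were open in both replicates, and Elavl3, Foxd3 and Nos1 had no region in either. Endothelial genes had one in 17.6% ± 16.6 of 17 against 45.2% (permutation adjusted p = 0.00747), with Ets1 open in both. Mesothelial genes had one in 18.2% ± 12.9 of 11 against 46.1% (permutation adjusted p = 0.0246), with Podxl open in both and Aldh1a2, Gpm6a and Tbx18 without a region. Kidney genes had one in 8.33% ± 11.8 of 12 against 33.0% (permutation adjusted p = 0.0327), and intestine genes in 6.67% ± 9.43 of 15 against 26.9% (permutation adjusted p = 0.0275). Cdx2, the intestinal homeobox gene, had no promoter region in either replicate, and Pdx1, a homeobox gene of pancreas and duodenum, had one in replicate 2 alone.

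Several calls depended on the lists used. With pseudoreplicated peaks only forebrain (56.7% against 82.9%) and the 3 Hox lists (46.7%, 25% and 12.5% against 76.7%, 92.1% and 86.8%) kept their calls below chance. Kidney (25% against 49.5%), endothelium (47.1% against 64.2%) and enteric nervous system genes (57.9% against 66.5%) stayed lower than chance without a call. Mesothelium (68.2% against 60.2%) and intestine (50% against 40.8%) stood higher than chance, also without a call. Stomach mesenchyme and Wnt then stood at chance (90% and 90.9%, each against 89.4%). Cell division had 100% with pseudoreplicated peaks (93.1% by chance), with the conservative list (83.9%) and without replicate 1 (85.4%). No higher share was possible there and none of the 3 could pass, so the missing calls say nothing about the list. Without replicate 2 it had 94.4% against 70.3% (permutation adjusted p = 0.0551). Stomach epithelium lost its call without replicate 1 (79.2% against 62.0%, permutation adjusted p = 0.136) and without replicate 2 (66.7% against 47.1%, permutation adjusted p = 0.0736), with differences from chance close to that of the mean of both. Red blood cells lost theirs without matching on CpG content (47.5% by chance, permutation adjusted p = 0.288). Stomach epithelium also lost its call with a 500 bp promoter window (68.8% against 53.8%, permutation adjusted p = 0.124), with equal numbers of top peaks (68.8% against 53.3%, 0.107) and with the pigment gene Pmel, first matched to the intestine list by mistake (0.0513). The intestine list had no call with Pmel either (13.3% against 31.5%, permutation adjusted p = 0.0635). Of the lists below chance, mesenchyme, endothelium, mesothelium, kidney and intestine lost their calls without replicate 1 but stayed lower than chance. Their shares were then 64%, 29.4%, 27.3%, 16.7% and 13.3%, against 80.2%, 52.0%, 51.4%, 38.2% and 31.5%. Mesothelium and kidney lost theirs with a 2 kb window, mesothelium also with the conservative list, and mesenchyme, mesothelium and Wnt without matching. Without matching 16 lists lay below chance, 8 of them among these 11, and housekeeping genes above it.

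**Figure D3:**
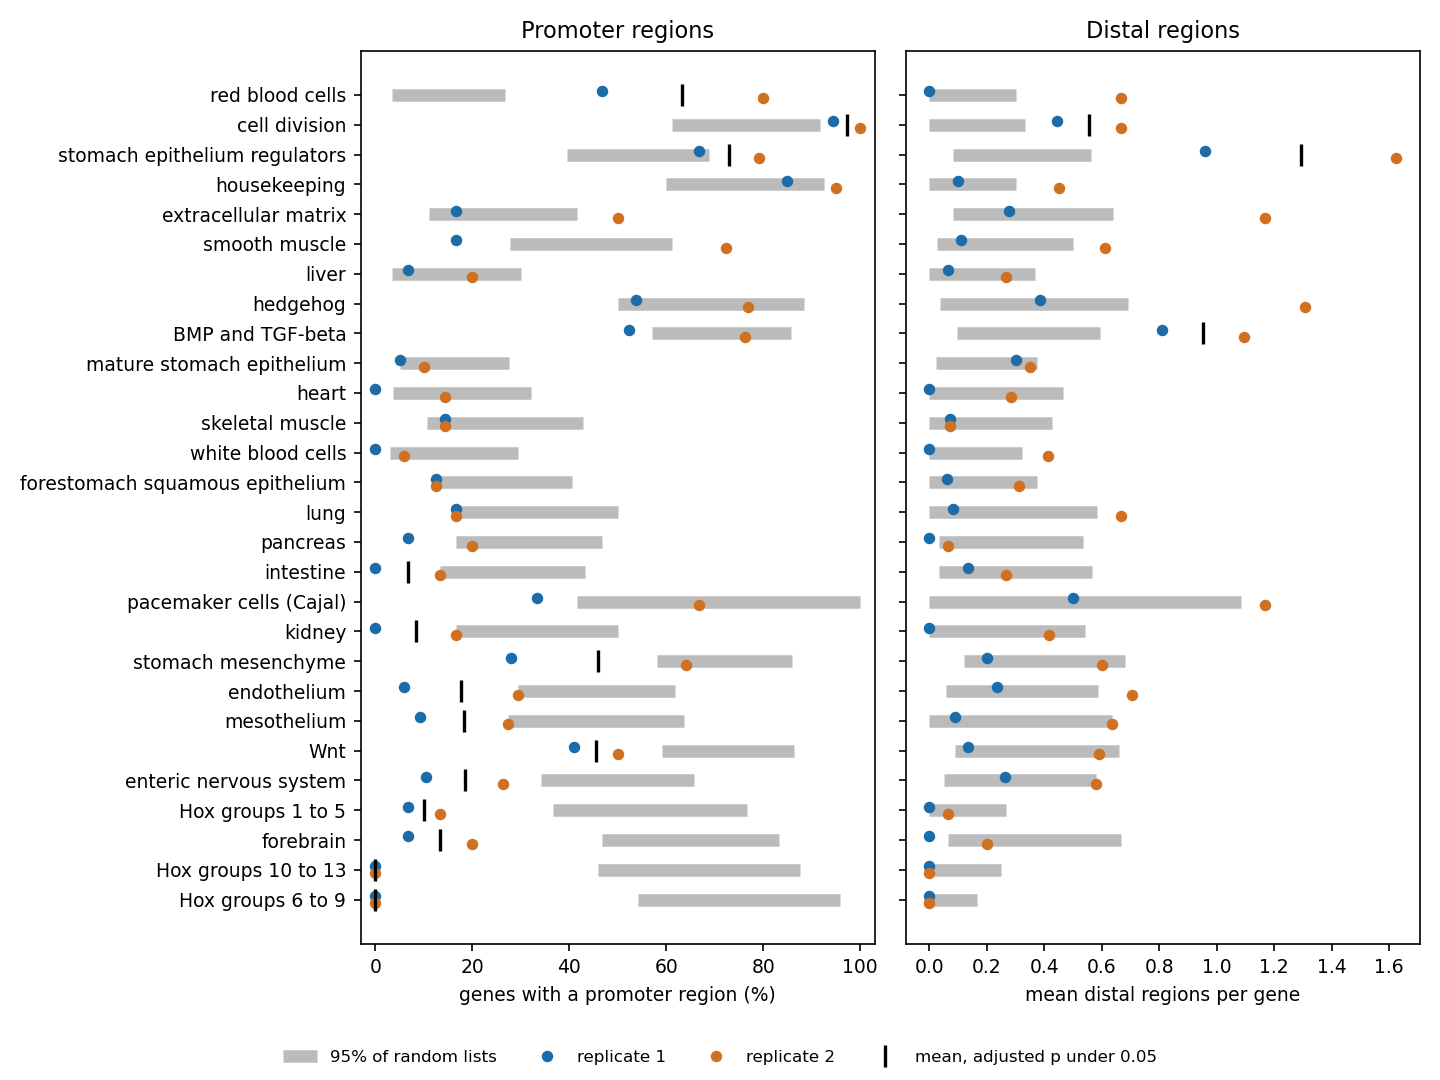
Share of each list's genes with a promoter region (percent, left) and mean number of distal regions per gene (right) in replicate 1 and replicate 2; grey bars hold 95% of matched random lists for the mean of the replicates, and a vertical tick marks that mean where its adjusted p was under 0.05. Red blood cells lie at 46.7% and 80%, above the grey bar, and Hox groups 6 to 9 and 10 to 13 at 0.

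The sixth comparison asked which genes had distal regions near them, meaning regions outside promoters assigned to the nearest coding start site within 100 kb. Stomach epithelium genes had a mean of 1.29 ± 0.471 distal regions (SD, n = 2) against 0.293 for random genes with as much assignable sequence, a ratio of 4.4. The values were 4.35 against 1.78 with pseudoreplicated peaks, and chance was 0.19 without matching. Elf3 had 3 in each replicate, Foxa2 1 in replicate 1 and 5 in replicate 2, and Grhl2 2 and 3. Shh had 2 and 3, Sox2 1 in each, and Gata4 3 and 1, while Hnf4a had none. Without Foxa2 the mean of the list was 1.22.

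Genes of BMP and TGF-beta signalling had a mean of 0.952 ± 0.202 against 0.31 (3.69 against 1.86 with pseudoreplicated peaks, and chance of 0.19 without matching), led by Smad6 (3 and 5) and Smad7 (4 in each), which encode inhibitory Smads, and with 1 and 3 at Id1, a BMP target. Cell division genes had 0.556 ± 0.157 against 0.128, with 2 in each replicate at Ccne1, 1 and 3 at Rrm2, and 2 and 1 at Cdk1. Of the 18 cell division genes, 12 had no distal region in either replicate, and without Ccne1 the mean was 0.471. The permutation test over 28 lists gave adjusted p = 0.0056, 0.0084 and 0.00933 for these 3 lists. The unadjusted p of stomach epithelium, 0.0002, is the smallest the random lists can give. In the same test 0 lists lay below chance, and 0 did so at an unadjusted p under 0.05. For many lists, among them heart, liver, kidney and lung, the grey bar of matched random lists already began at 0. No count could lie below that bar, so the missing calls say nothing about these lists. Without replicate 1 the BMP and cell division calls were lost, although the means stayed higher than chance (1.10 against 0.463 and 0.667 against 0.19). Cell division also lost its call with the conservative list (permutation adjusted p = 0.0812), with pseudoreplicated peaks (0.0616) and without matching (0.0896). Hedgehog genes were above chance with assignment within 500 kb (permutation adjusted p = 0.0462) and without matching (0.0084), as were matrix genes without matching (0.0084) and Wnt genes with pseudoreplicated peaks (0.0373).

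Of the other gut regulators named beforehand, Barx1 had 3 distal regions in replicate 2 and none in replicate 1. In the conservative list these lay on chromosome 13 between the gene and 98112 bp from its start site, at 48694131 to 48695297, 48731070 to 48732008 and 48760731 to 48761490, all intergenic. Cdx2 had 2 and 1, of which the conservative list held 2 on chromosome 5, at 147293141 to 147293785 and 147299220 to 147300233. Foxf1, Nkx2-5 and Pdx1 had none in either replicate. Of the 3 regions assigned to Shh in the conservative list, the strongest (signal 11.3) lay on chromosome 5 at 28500809 to 28501691, 33993 bp from the start site.

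By the mean of the replicates within 100 kb, the gene with most distal regions was Lipc, the hepatic lipase gene, with 4 in replicate 1 and 11 in replicate 2 and no promoter region. Gse1 had 4 and 10, and more than Lipc in the conservative list (10 against 7) and with pseudoreplicated peaks (26.5 against 14), and Pde4d, a cyclic AMP phosphodiesterase gene, 5 and 9. The cytoplasmic actin gene Actg1 had 5 and 6, and Kalrn, a Rho exchange factor gene, 3 and 8. Irf2bpl, Ptma and Tbxas1 each had 4 and 6, Ncor2, a nuclear corepressor gene, 3 and 7, and Sh3pxd2a 2 and 8. Within 25 kb, Kalrn and Tbxas1 had a mean of 4.5 and Lipc 2.5. The mean over all 21829 coding genes was 0.19.

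In the epithelium of the stomach, several genes of mature cells had no region in either replicate. These included Atp4b, a subunit of the acid pump, Gast, the gastrin gene, and Chia1, an acidic chitinase gene. Of the squamous epithelium list, Dsc3 and Dsg3, which encode desmosomal cadherins, and Ivl, the involucrin gene, had none. Of smooth muscle genes, Cald1 and Cnn1 had none, although the conservative list held 1 distal region of Cnn1. With pseudoreplicated peaks 16 of the 18 smooth muscle genes had a promoter region in replicate 1. All 18, these 2 genes included, had one in replicate 2. A missing region means that none passed the authors' threshold, not that the chromatin was closed in every cell.

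The seventh comparison asked whether Hox genes, which are ordered along the body axis, were open by position. Hoxa1 was the only Hox gene of the 3 lists with a promoter region in both replicates, on chromosome 6 (gene at 52155590 to 52158317). Hoxa5 had one in replicate 2 alone, and Hoxa4 had 1 distal region in replicate 2. That made 1 of 15 genes in groups 1 to 5, 0 of 12 in groups 6 to 9 and 0 of 12 in groups 10 to 13. Fisher's exact test of groups 1 to 5 against 10 to 13, two-sided, gave p = 1. With only 1 open gene in these groups the test could not pass wherever that gene lay, so it does not answer the question. With pseudoreplicated peaks the counts were 4, 2 and 0 (Fisher's exact p = 0.106). All genes of the tested groups that were open in both replicates then lay in groups 1 to 5, and even that was too few to pass. Taken by itself, replicate 2 had a promoter region in 9 of 15 genes of groups 1 to 5. In groups 10 to 13 it had one in 3 of 12. Fisher's test also counts neighbouring Hox genes as independent.

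The eighth comparison asked which sequence motifs lay within 100 bp of distal summits, against flanking windows 600 bp away. Of 35 motifs, 10 were enriched in both replicates. The motif of CTCF, the insulator protein, was found at 2.03% of summits and 0.165% of flanks, with log2 ratios of 3.77 and 3.53 (mean 3.65 ± 0.17, SD, n = 2). The motif of KLF and SP factors had a mean log2 ratio of 2.45 ± 0.47, and the longer GATA motif 2.06 ± 0.11, at 11.4% of summits and 2.73% of flanks. The HNF4 motif had 1.70 ± 0.17 and the AP-1 motif of FOS and JUN factors 1.64 ± 0.07. The order differed against GC-matched windows, where the KLF and SP motif had 1.83, below the longer GATA motif (2.60) and HNF4 (2.33). The short GATA motif and those of forkhead, TEAD and NF-Y factors and the CAGCTG E-box were enriched too.

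The ATTA motif of BARX and HOX homeodomains was depleted, at 1.31% of summits and 2.97% of flanks (mean log2 ratio -1.18 ± 0.04), as was the CDX motif (-0.95 ± 0.02). The PBX motif had a mean of -1.01 ± 0.34 and was not called. A call needed a ratio over 1.2, or its inverse, with a Bonferroni-corrected counting interval that excluded 1 in each replicate. Against random windows matched on GC content no motif was depleted (mean log2 0.10 for the ATTA motif, 0.021 for PBX and -0.12 for CDX), and NF-Y was not enriched. A motif stands for a family of factors and does not show which factor was bound.

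**Figure D4:**
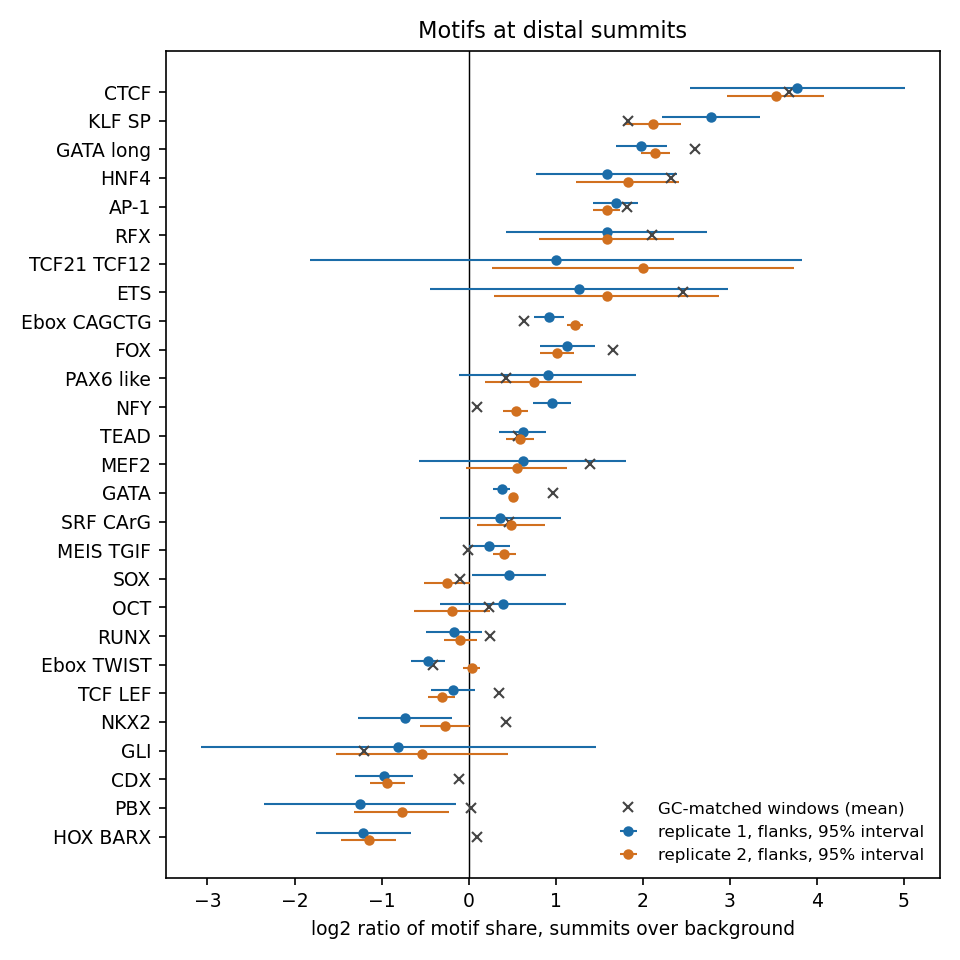
Log2 ratio of the share of distal summits with each motif over the share of flanking windows, for replicate 1 and replicate 2 with uncorrected 95% counting intervals, and the mean ratio against GC-matched random windows as crosses. CTCF is highest at 3.77 and 3.53, and the ATTA motif of BARX and HOX factors moves from -1.18 to 0.10 with GC matching.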

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

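The ranked lists, which no comparison of the report used for single replicates, held peaks that the thresholded lists did not. In replicate 1, 162 ranked peaks had a score of at least 540 but were absent from the thresholded list as read here, and in replicate 2 170 were. Of these, 32 and 42 lay on other sequences of the assembly. Such peaks had been dropped from the thresholded lists beforehand, so their absence says nothing. The others, 130 and 128, lay on chromosomes 1 to 19, X and Y, in 59 and 56 merged regions. The one with the lowest p value in each replicate lay on chromosome 1 from 24611586, ending at 24616166 in replicate 1 and 24616165 in replicate 2 (mm10), 26403 bp from the start site of Col19a1, a collagen gene. At any score, the ranked lists held 140 peaks in replicate 1 and 139 in replicate 2 on other sequences of the assembly. The ranked lists, unlike the thresholded ones, were made without the exclusion list, per the submitters' processing notes. Whether that list removed the 130 and 128 peaks was not tested.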

How the results depend on the processing

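The alternatives with equal numbers of top peaks for the gene lists and with Pmel were chosen after the data had been seen. Of the alternative values of the main results, 66 kept the outcome and 11 did not; the cause was not tested. An outcome was kept if a share stayed above chance, a count of lists or motifs stayed within 1.5 times, a test stayed on its side of 0.05, or a correlation or unmatched share stayed in its interval. Kept outcomes include changed values, such as a promoter share of 41.6% with pseudoreplicated peaks against 71.4%. The rank correlation was 0.679 past the IDR threshold and 0.498 without promoter peaks. Against pseudoreplicated peaks the promoter share of unmatched regions was 47.7% in replicate 1 and 28.4% in replicate 2. Promoter lists above chance numbered 3, and 1 to 1 without a replicate (red blood cells each time). Lists below chance numbered 11, 6 to 11 without a replicate, 4 with pseudoreplicated peaks, all 4 among the 11, and 16 without matching on CpG content, of which 8 were among the 11. Distal lists above chance numbered 3, and 1 to 3 without a replicate. Depleted motifs numbered 2, then 1 with 50 bp windows and 0 with GC matching. With pseudoreplicated peaks 4 lists went from below to above their chance mean: stomach mesenchyme (90% against 89.4%), mesothelium (68.2% against 60.2%), intestine (50% against 40.8%) and Wnt (90.9% against 89.4%), none with a call. With GC matching the mean log2 ratio of the ATTA motif was 0.10 and of PBX 0.021. Of the values of single lists, motifs and genes, 315 kept their call and direction (or, for counts of distal regions of a gene, stayed within the SD of the replicates), 31 lost the call (3 of them cell division promoters at 100%, where no call was possible), 6 changed direction (those above) and 72 moved, all of them such counts. No paired analysis was possible because the series has 1 group only. A replicate left out leaves 1 sample, whose p values come from random gene lists and not from a spread between samples.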

Other observations

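The tests of mitochondrial matches, repeated sequence, neighbouring genes, a second red blood cell list, equal numbers of top peaks and the replicate difference per list were chosen after the patterns had been seen, and the bounds for unmatched regions were written after their result. In the IDR-thresholded lists smooth muscle genes differed most between the replicates: 3 of 18 had a promoter region in replicate 1 (16.7%) and 13 in replicate 2 (72.2%), a mean of 44.4% against 43.4% by chance. Acta2 (smooth muscle actin), Myh11 (smooth muscle myosin), Tagln (transgelin) and Myocd (myocardin) were open in replicate 2 alone. With equal numbers of top peaks the difference was 22.2 points, and 5 lists differed more: red blood cells and pacemaker cells (33.3 points each), extracellular matrix (27.8), stomach mesenchyme (24) and endothelium (23.5). With pseudoreplicated peaks it was 11.1 points, from 88.9% and 100%, so close to the highest share possible that it says little. Extracellular matrix genes then differed most (44.4 points, permutation adjusted p = 0.0112), and no other list passed. Extracellular matrix genes had 16.7% and 50%, with Col1a2 and Fn1 open in both and Col3a1 and Eln in replicate 2 alone. With pseudoreplicated peaks both lists lay above chance, at 94.4% against 62.8% and 66.7% against 42.9% (adjusted p = 0.0014 and 0.0385, permutation test). Hedgehog genes had 0.846 ± 0.653 distal regions (SD, n = 2) against 0.304, which did not pass adjustment (permutation p = 0.0212, adjusted 0.148), with 2 and 3 at Shh. They passed it with assignment within 500 kb (1.15 against 0.385, permutation adjusted p = 0.0462) and without matching (permutation adjusted p = 0.0084).

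The remaining lists did not pass the promoter test with CpG matching in the full IDR-thresholded lists. Housekeeping genes had a promoter region in 90% against 77%, hedgehog genes in 65.4% against 69.6%, BMP and TGF-beta genes in 64.3% against 72.0% and pacemaker cell genes in 50% of 6 against 71.3%. Genes of mature stomach epithelium had one in 7.50% against 15.7%, with Esrrg, an orphan nuclear receptor gene, open in both replicates, and squamous forestomach genes in 12.5% against 25.2%. White blood cell genes had 2.94% against 14.7%, pancreas 13.3% against 32.1%, liver 13.3% against 13.9% and lung 16.7% against 32.7%. Heart genes had 7.14% against 18.3% and skeletal muscle genes 14.3% against 26.0%. Without matching, housekeeping genes were above chance (90% against 47.9%, permutation adjusted p = 0.00187). The lists of mature epithelium, squamous forestomach, white blood cells, pancreas, liver, lung, heart and skeletal muscle were then below it (permutation adjusted p from 0.00187 to 0.0401). With equal numbers of top peaks white blood cell genes were below chance with matching (permutation adjusted p = 0.0404).

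Replicate 2 listed 1.72 times as many regions as replicate 1. Of its 9190 unmatched regions, 6737 (73.3%) were found among the pseudoreplicated peaks of replicate 1. A lower sensitivity of the replicate 1 list would need such recovery. Of the 722 unmatched regions of replicate 1, 657 (91.0%) were found among those of replicate 2. The shares are not like for like, as the pseudoreplicated lists held 34450 regions in replicate 1 and 60371 in replicate 2. Recovery was thus seen in both directions, and lower sensitivity is only a candidate. The smooth muscle difference was 55.6 points (adjusted p = 0.0112, permutation test). With equal numbers of top peaks it was 22.2 points, below 27.8, a value that few random lists exceeded (adjusted p = 1, permutation test). That setting left replicate 2 with 17194 merged regions against 11633, and random lists with a mean difference of 11.7 points, so list length was not made equal; a larger share of muscle cells in the second pool cannot be told apart from it, since the value lay between the bounds set beforehand. Other differences between the pools remain open: red blood cell genes differed with equal numbers of top peaks and matrix genes with pseudoreplicated peaks, but 1 sample per pool does not separate cell content from processing.

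The 10 strongest regions lay at least 11179 bp from coding start sites. Of these, 4 matched the mitochondrial genome at 90% identity or more over at least 50% of their length, against 0 of 100 random regions (Fisher's exact test, p = 3.64e-05). The region nearest to Abcb11, second by signal, fell just short, with 100% identity over 48.5% of its length. Copies of mitochondrial DNA in the nuclear genome may account for part of the pattern, but 5 of the 10, among them the one near Pak3, had no match. The count of 4 lay between the bounds set beforehand for the whole set. Counted without the length limit, 5 regions matched, which would reach the upper of those bounds. Further copies in the assembled nuclear chromosomes, at 90% identity or more over at least 80% of the length, were argued against as the cause for the set. Of the 10 regions, 8 had no such copy and 0 had 2 or more. For the other 2, nearest to G6pd2 and Tyrp1 and with 1 copy each, they are not excluded, as 2 of 100 random regions had any. Shorter or more diverged repeats, and copies missing from the assembly, could not be seen by this search. No biological explanation was tested.

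Red blood cell genes had the highest ratio to chance of the promoter lists matched on CpG content (4.58), but were not above chance without that matching (63.3% against 47.5%, permutation adjusted p = 0.288). Of the 12 open in a replicate, 0% shared their region with a coding start site of a gene outside the list, against 24.1% and 21.3% of all open genes, which argues against neighbouring genes as the source. Red blood cells in the pools are a candidate source. A second list of 19 red blood cell genes, 0 of them in the other lists, had 47.4% against 36.7% by chance. Its shares were 26.3% in replicate 1 and 68.4% in replicate 2. The mean lay below 50%, a value that few random lists exceeded (permutation p = 0.154). With pseudoreplicated peaks the mean was 68.4% against 49.9% by chance (permutation p = 0.014), from 57.9% in replicate 1 and 78.9% in replicate 2. With the thresholded lists that source cannot be told apart from chance, since the value lay between the bounds set beforehand; of the globin genes, Hbb-bt and Hbb-bs were open in both replicates and Hba-a1 and Hba-a2 in replicate 2 alone, while Hbb-y, Hbb-bh1 and Hba-x were open in neither. In replicate 2 the first list was 33.3 points higher than in replicate 1, also with equal numbers of top peaks (adjusted p = 0.0224, permutation test), while with pseudoreplicated peaks both stood at 93.3%, too close to the highest share possible for their difference of 0 points to count against it.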
